A study of Mus musculus with 4 samples.

How the data were processed

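Liver of adult male C57Bl/6 mice was profiled by poly-A selected, stranded RNA sequencing. Per the labels' protocols, mice aged 10 to 12 weeks received 0.75 x E11 genome copies of AAV8-STAT5ca or AAV8-Null per mouse by tail vein, and livers were taken 2 weeks later, at 12 to 14 weeks of age. The labels describe the starting material as total liver RNA in one place and as nuclear liver RNA in another, which would change the balance of unspliced and noncoding transcripts; the sources used here do not settle it. The labels number the 2 males of each group 1 and 2, with no statement that a number pairs animals.

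The submitters' processing notes name the mm9 build, STAR, featureCounts and edgeR, with no versions and no counting options. The authors deposited 1 table for the whole series, and its rows hold, per the file headers, 1 RPKM value for each group (reads scaled by gene length and library size), a signed linear fold change and an edgeR adjusted p-value. The fold change is written by the authors as a value of at least 1 where STAT5ca is higher and of at most -1 where it is lower. The table also lists mm9 positions, which are printed as given. It has 75794 rows with values and 4 emptied rows, and 38863 rows are at 0 in both groups. Rows are named by gene symbol or, for noncoding transcripts, by a numbered identifier with the prefix nc_inter, nc_as or nc_intra.

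The design planned before the data were examined was edgeR's quasi-likelihood test on counts per sample, which the authors' deposited table cannot supply since it holds neither counts nor values per sample. For the same reason the planned limma fit on values per sample, camera and fry were not run on it. The authors' own adjusted p-values, at a threshold of 0.05, took the place of that test. The log2 fold changes are the log2 of the authors' fold changes, whose offset from the plain ratio of the 2 RPKM values has a median of 0.048 on the log2 scale over 5718 genes at 5 RPKM or more in both groups, a scaling factor of 1.03. A fold change is not given where a group is listed at 0.

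A set of 23 gene lists (373 genes, of which 372 are in the table) was fixed before the data were examined: male-biased, female-biased, STAT5-responsive, cell cycle, interferon response, acute phase, cholesterol synthesis, lipogenesis, fatty acid oxidation, bile acid, pericentral, periportal, circadian clock, stress and p53, fetal and tumour markers, Kupffer cell and macrophage, lymphocyte, neutrophil, stellate cell and fibroblast, endothelial, cholangiocyte, erythroid and reference genes. Of the 7 erythroid names, 2 repeat the position and fold change of another, so the values given for that list use 5 genes; all 7 names remain in the counts over all lists and in the figure. For each list the members past the threshold were counted. The median log2 fold change of its measured members was placed among those of 10000 random lists of the same size, drawn from 20 bins of mean RPKM over both groups. A count adjusted over the list alone used an upper bound of each unadjusted p-value, the authors' adjusted p-value times its rank divided by 36931, the number of rows above 0. It is an upper bound only if the authors adjusted over at least that many rows, which is not known. In simulated data with a known number of rows this bound was never below the true value. Of simulated lists, 100 of 100 shifted by 1 on the log2 scale fell outside the central 95% of their random lists, and 9 of 100 unshifted lists did.

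The genes named in the text follow a rule fixed before the data were examined. It takes 9 genes always (Stat5b, Stat5a, Cish, Socs2, Igf1, Bcl6, Cux2, Cyp2b9 and Cyp2d9), the 5 largest changes each way among called symbols, the 4 largest called members of the male-biased, female-biased and STAT5-responsive lists and the 2 largest of every other list. The rule's expression minimum of 10 CPM was applied as 10 RPKM in a group, and its demand that libraries separate was left out since the table has no libraries. Other members of the lists, and genes outside them, were chosen after their values were seen. Some genes that the rule takes are not reported here, and the counts include them.

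Depth was recovered from the values. For rows with 1 interval, RPKM times the listed length falls on whole-number combinations of 2 steps per column. Each column is therefore the mean of 2 libraries with totals of 19407646 and 20024694 reads (Null) and 20294333 and 21021777 reads (STAT5ca). Within a group, library a is the smaller and b the larger, with no link to the animals' numbers. With these totals, the RPKM of each library was solved for low-level rows as the only whole-read solution within a relative tolerance of 5.5e-08, using gene lengths between 0.25 and 1.3 times the exon union of GENCODE vM21 for symbols and the listed length for noncoding rows. A unique solution was found for 7592 of 8072 symbol rows tried and 16363 of 19578 noncoding rows, against 2.90% and 0.00511% when the values were shifted slightly. On simulated libraries 4 of 4 totals and 497 of 499 genes gave a unique solution, and 497 of 497 of those were the true reads. Rows with more than 400 reads in a group (2000 for noncoding rows) were not tried, so most abundant liver genes have no library values.

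The recovered reads, in the smallest whole numbers that fit, were tested with limma-voom on the recovered library totals, with no further scaling, for 6746 rows with at least 20 reads over the 4 libraries. In a simulation of the STAT5ca against Null comparison on those 6746 rows, with 200 rows changed, it recovered 27 at 2-fold, 158 at 4-fold and 199 at 8-fold, with 0, 2 and 3 unchanged rows called. Medians of marker lists were compared by a two-sided permutation test with 100000 resamples. Runs of called rows along chromosomes were compared with 1000 shuffles of the calls. With 2 samples against 2, an exact permutation test of a single value cannot give a p-value below 0.333.

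The alternatives tried were an adjusted p below 0.01, rows with a mean of at least 1 RPKM, a new adjustment over 17681 rows with a mean of at least 0.1 RPKM, RPKM ratios with pseudocounts of 0.1 and 1, random lists matched on Null RPKM, erythroid names with repeats of a locus, and limma-voom with other read minimums and without each recovered library. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.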

Results

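Gene expression was measured by stranded, poly-A selected RNA sequencing of liver from adult male C57Bl/6 mice. The mice had received an adeno-associated virus of serotype 8, a vector that mainly enters hepatocytes, by tail vein 2 weeks earlier. In the STAT5ca group the vector carried a constitutively active form of STAT5b, a transcription factor that growth hormone activates in liver. The Null group received the Null vector at the same dose as its control. Each group held 2 samples, 4 in all. The comparison of STAT5ca with Null asks which liver genes respond when STAT5 activity is persistent, and whether genes with a sex bias in mouse liver shift in males. Growth hormone release is pulsatile in male mice and more continuous in females, so liver STAT5 activity is intermittent in males. The authors' deposited table gives 1 RPKM value per group and gene, 1 fold change and 1 adjusted p, with no value per sample, so no SD accompanies the levels. Whole reads could still be read out of the low values. They gave library totals of 19407646 and 20024694 reads in Null and of 20294333 and 21021777 reads in STAT5ca, and 1 read in 1 library of a 1 kb gene adds 0.0238 to 0.0258 to a group RPKM. At 0.1 RPKM a gene of 1 kb therefore rests on a handful of reads, and a longer gene on more.

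Stat5b itself (chromosome 11, 100642045 to 100711895, mm9) was at 6.84 RPKM in Null and at 15.5 RPKM in STAT5ca in the authors' deposited table, 2.21-fold higher with an adjusted p of 0.000132. Reads of the vector transcript cannot be told apart from those of the mouse gene where their sequences are shared. The neighbouring paralog Stat5a was at 3.70 and 3.61 RPKM, with an adjusted p of 1 in the authors' deposited table.

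Of 75794 genes listed, 36931 were above 0 in at least 1 group, and 2031 of them differed at an adjusted p below 0.05 in the authors' deposited table. More of these calls were higher in STAT5ca (1433) than lower (598), and 1568 had at least a 2-fold change, 1245 of them higher and 323 lower. Genes with a symbol made up 1432 of the calls in the authors' deposited table (953 higher and 479 lower), and the other 599 were numbered noncoding transcripts, of which 480 were higher. The excess of higher calls depended on level. Among genes with a mean of at least 1 RPKM, 535 of 986 calls in the authors' deposited table were higher (54.3%), against 898 of 1045 (85.9%) below that level. At a mean of 10 RPKM or more, 149 of 412 calls in the authors' deposited table were higher (36.2%), so that most calls among abundant transcripts were lower. The median log2 fold change of genes at 1 RPKM or more in both groups was -0.07 in the authors' deposited table.

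Female-biased genes rose in the livers of STAT5ca males. Of 37 measured genes in a list fixed before the data were examined, 25 were higher and 0 were lower in the authors' deposited table, and 26 were higher and 3 lower when p was adjusted over the list alone. The list's median log2 fold change was 2.29, above all of 10000 random gene lists matched on expression. A1bg (chromosome 15, 60749144 to 60752825, mm9), a secreted glycoprotein gene, went from 7.61 to 1023 RPKM, 131-fold higher with an adjusted p of 1.31e-131 in the authors' deposited table. The sulfotransferase gene Sult3a1 (chromosome 10, 33577528 to 33599281) rose 117-fold, from 1.75 to 210.8 RPKM, with an adjusted p of 9.23e-118 in the authors' deposited table. Cux2 (chromosome 5, 122310225 to 122499860), a homeobox repressor specific to female liver, rose 96.8-fold from 0.124 to 12.3 RPKM, with an adjusted p of 4.33e-59 in the authors' deposited table. The change of Cux2 was 6.60 on the log2 scale and 5.79 for the RPKM ratio with a pseudocount of 0.1. Cytochrome P450 genes of steroid and drug metabolism rose with them: per the authors' deposited table, Cyp3a41b was 96.7-fold higher (adjusted p = 1.79e-56) and Cyp2b9 35.4-fold higher (adjusted p = 3.92e-53). Cyp2a4 went from 6.76 to 607 RPKM in the authors' deposited table. The prolactin receptor gene Prlr rose from 5.70 to 105.1 RPKM in the authors' deposited table (adjusted p = 5.65e-61). Cyp3a41b, Sult3a1 and Cyp2a4 have near-identical paralogs, so the split of reads among family members is uncertain. The response was not uniform. Cyp2b10 was at 3.59 and 4.12 RPKM, Cd36 at 18.3 and 16.3 and Tox at 1.59 and 0.954 in the authors' deposited table, none past the threshold.

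Male-biased genes moved the other way. Of 25 measured members, 16 were lower and 1 was higher in the authors' deposited table (17 and 2 when adjusted over the list alone), and the median log2 fold change of -1.15 lay below all 10000 random lists. Elovl3 (chromosome 19, 46206387 to 46210184), a fatty acid elongase gene, fell from 83.9 to 0.918 RPKM, 93.6-fold lower with an adjusted p of 8.27e-107 in the authors' deposited table. Cyp2d9, a steroid hydroxylase gene, fell from 790.8 to 133 RPKM, 6.15-fold lower with an adjusted p of 5.67e-36 in the authors' deposited table. Bcl6, a repressor that occupies STAT5 sites in male liver, was 2.22-fold lower, at 5.71 and 2.63 RPKM, with an adjusted p of 0.000751 in the authors' deposited table. Cyp7b1, an oxysterol hydroxylase gene, was the exception that rose, from 83.1 to 197 RPKM in the authors' deposited table (adjusted p = 5.06e-07). Moxd1 was at 1.28 RPKM in Null and 10.3 in STAT5ca in the authors' deposited table, with an adjusted p of 0.113.

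Of the 5 largest decreases among called symbols at 10 RPKM or more in a group, 4 were in the major urinary proteins, the pheromone carriers that male liver secretes in bulk, and the other was Elovl3. Of 20 measured Mup genes, 18 were lower and 0 were higher in the authors' deposited table, by 2.39 to 136 times, and their summed level went from 53094 to 6683 RPKM. Mup17 (chromosome 4, 61252963 to 61256864) fell from 1952 to 15.1 RPKM (adjusted p = 6.97e-77), Mup1 from 310.8 to 3.41 RPKM (adjusted p = 1.1e-120), Mup14 from 3607 to 43.8 RPKM (adjusted p = 5.81e-85), Mup12 from 93.6 to 1.21 RPKM (adjusted p = 2.31e-65) and Mup7 from 6053 to 155 RPKM (adjusted p = 6.67e-69) in the authors' deposited table. Mup3 had the highest level of the family in STAT5ca, at 2319 RPKM against 5390 in Null in the authors' deposited table. Members of this family share long stretches of sequence, so values of single Mup genes are uncertain.

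**Figure D1:**
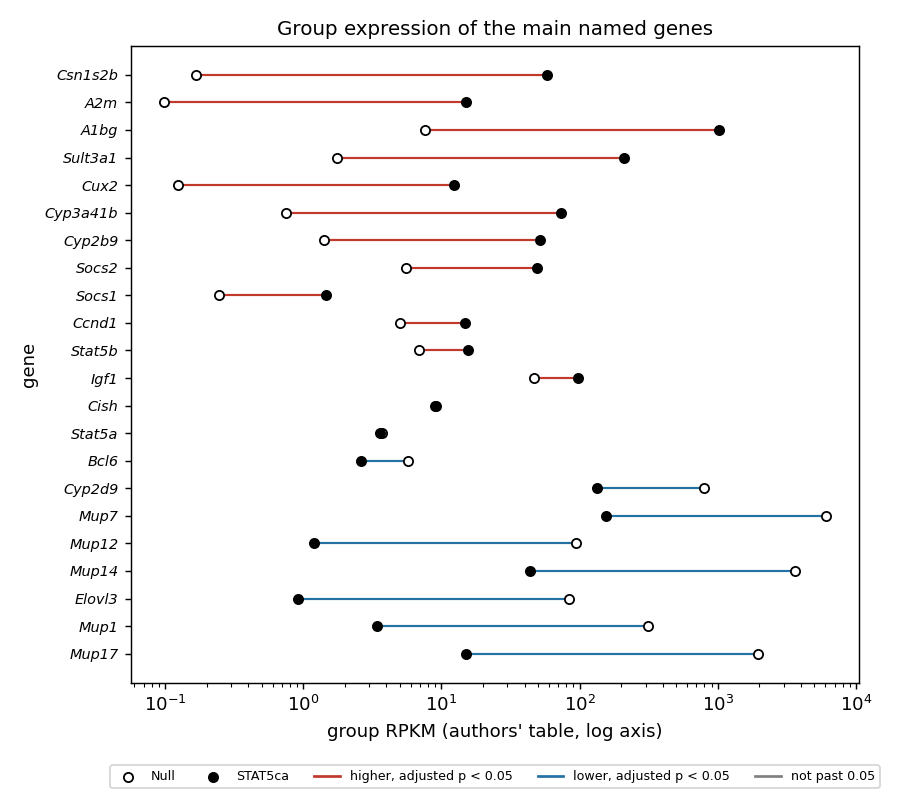
Group expression of 22 named genes, with 1 open point for Null and 1 filled point for STAT5ca per gene on a log axis of RPKM from the authors' deposited table; line colour gives the direction for genes past an adjusted p of 0.05. A1bg went from 7.61 to 1023 RPKM while Mup17 went from 1952 to 15.1 RPKM, and Cish and Stat5a lay at nearly the same level in both groups. Csn2 is not drawn, since it was listed at 0 in Null.

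A pair of casein genes, milk protein genes that STAT5 drives in the mammary gland, were among the largest increases. Csn2, the beta-casein gene (chromosome 5, 88121644 to 88128450), was listed at 0 in Null and at 13.6 RPKM in STAT5ca, with an adjusted p of 1.75e-18 in the authors' deposited table. Csn1s2b, a second casein gene of the same cluster, rose 318-fold from 0.167 to 58.3 RPKM in the authors' deposited table (adjusted p = 3.33e-57). A2m, the alpha-2-macroglobulin gene, rose 147-fold from 0.0985 to 15.1 RPKM (adjusted p = 8.48e-112) in the authors' deposited table. Its change was 7.20 on the log2 scale and 6.26 for the RPKM ratio with a pseudocount of 0.1.

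Genes that growth hormone or cytokines induce through STAT5 responded in part. Of 17 measured, 5 were higher and 1 was lower in the authors' deposited table (6 and 1 when adjusted over the list alone), and the median log2 fold change of 0.18 lay at percentile 99.6 of the random lists. Socs2, a feedback inhibitor of growth hormone signalling, rose 8.51-fold from 5.58 to 49.4 RPKM (adjusted p = 6.49e-18), and Socs1 rose 5.62-fold from 0.248 to 1.45 RPKM (adjusted p = 1.91e-06) in the authors' deposited table. The growth factor gene Igf1 rose 2.00-fold from 46.8 to 96.7 RPKM (adjusted p = 8.38e-06) and the cyclin gene Ccnd1 rose 2.86-fold (adjusted p = 6.31e-12) in the authors' deposited table. Cish, another STAT5 target and feedback inhibitor, was at 8.93 RPKM in Null and 9.19 RPKM in STAT5ca, with an adjusted p of 1 in the authors' deposited table. The NADPH oxidase gene Nox4 fell from 13.1 to 7.0 RPKM in the authors' deposited table (adjusted p = 0.00131).

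Many cell cycle genes were higher. Of 30 measured cell cycle genes, 20 were higher and 0 were lower in the authors' deposited table, 24 when adjusted over the list alone, and the median log2 fold change of 2.05 lay above all 10000 random lists. The proliferation marker Mki67 rose 12.4-fold, from 0.179 to 2.31 RPKM, with an adjusted p of 1.6e-41 in the authors' deposited table. The spindle gene Nusap1 was at 0.0254 RPKM in Null, a level of few reads, and at 0.714 RPKM in STAT5ca (adjusted p = 3.51e-13) in the authors' deposited table. Ccnb1 rose from 0.186 to 1.52 RPKM and Cdc20 from 0.326 to 3.46 RPKM in the authors' deposited table. Among genes of S phase and of replication licensing, Mcm6 rose from 0.677 to 1.55 RPKM, while Mcm2 was at 0.869 and 1.35, Pcna at 17.9 and 18.1 and Ccne1 at 0.730 and 0.709 RPKM in the authors' deposited table. Whether mitosis and S phase genes differ in response was not tested. Markers of Kupffer cells and macrophages were higher in the same livers, with a median log2 fold change of 1.00 in the authors' deposited table. The median was 0.93 for lymphocyte genes, of which 5 of 16 were called, and 1.46 for neutrophil genes, of which 1 of 7 was called. Much of the neutrophil shift lay in STAT5ca library b, where S100a8 was at 5.99 RPKM against 0.380 in library a. The table does not show which cells carry the cell cycle transcripts.

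Most interferon-response genes were higher. Of 22 measured, 16 were higher and 0 were lower in the authors' deposited table, 21 when adjusted over the list alone, with a median log2 fold change of 1.65 that lay above all 10000 random lists. Ifi44 rose 7.05-fold from 0.712 to 5.23 RPKM (adjusted p = 1.71e-11) and the guanylate-binding protein gene Gbp3 rose 6.42-fold from 1.33 to 8.88 RPKM (adjusted p = 3.18e-18) in the authors' deposited table. Isg15 went from 6.52 to 29.2 RPKM and the transcription factor gene Irf7 from 13.3 to 55.7 RPKM, both past the threshold in the authors' deposited table. The 4 members with recovered reads were higher in STAT5ca library b than in library a: Oas1a at 3.20 RPKM in a and 6.37 in b, Gbp2 at 2.46 and 4.59, Ifit2 at 1.73 and 2.36 and Mx1 at 0.981 and 1.65. Null libraries a and b showed the same order: Oas1a at 0.959 and 1.41 RPKM, Gbp2 at 1.26 and 2.04, Ifit2 at 0.437 and 0.580 and Mx1 at 0.400 and 0.404. Markers of Kupffer cells were also higher in these livers, with a median log2 fold change of 1.00 in the authors' deposited table.

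Acute phase genes gave 3 higher and 0 lower of 21 in the authors' deposited table (5 and 0 when adjusted over the list alone), and their median log2 fold change of 0.42 lay above all 10000 random lists. Apcs, the serum amyloid P gene, rose 4.48-fold from 67.3 to 316.9 RPKM (adjusted p = 1.25e-07) and Itih4 rose 2.17-fold from 576 to 1309 RPKM (adjusted p = 0.0123) in the authors' deposited table. The classical acute phase genes Saa1, at 769 RPKM in Null and 467 in STAT5ca, and Hp, at 2614 and 2911, had an adjusted p of 1 in the authors' deposited table. Of 12 stress and p53 genes, 2 were higher and 2 were lower in the authors' deposited table (3 and 2 when adjusted over the list alone), with a median log2 fold change of 0.19 at percentile 97.8 of the random lists. The cell cycle inhibitor gene Cdkn1a rose 3.73-fold (adjusted p = 6.07e-08) and Atf3 rose 3.60-fold (adjusted p = 1.47e-05), while Herpud1 fell from 175 to 75.8 RPKM in the authors' deposited table.

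Markers of other cell types did not move alike. Of 12 Kupffer cell and macrophage genes, 10 were higher and 0 were lower in the authors' deposited table, the same numbers as when adjusted over the list alone, with a median log2 fold change of 1.00 above all 10000 random lists. Cd68 rose 2.51-fold (adjusted p = 6.64e-06) and Cd5l rose 2.27-fold, from 19.9 to 47.2 RPKM (adjusted p = 4.49e-05), in the authors' deposited table. Of 16 lymphocyte genes, 5 were higher and 0 were lower in the authors' deposited table (6 and 0 when adjusted over the list alone), with a median log2 fold change of 0.93 at percentile 97.54 of the random lists. These calls lay near the threshold: 1 of the 5 was below an adjusted p of 0.01, and limma-voom on recovered reads called 0 of the 12 tested lymphocyte genes, 4 of them called by the authors, with 4 of the 12 at an unadjusted p below 0.05. The granzyme gene Gzma was at 0.0294 and 0.496 RPKM (adjusted p = 0.0168) in the authors' deposited table. The T cell gene Cd3e was at 0.178 RPKM in Null and 0.233 RPKM in STAT5ca, with an adjusted p of 1 in the authors' deposited table. Of 7 neutrophil genes, only Cxcr2 passed, at 0.0169 and 0.151 RPKM (adjusted p = 0.0364) in the authors' deposited table, while 3 passed when adjusted over the list alone and the median log2 fold change was 1.46, at percentile 98.3. Much of this shift lay in 1 STAT5ca library: by recovered reads, S100a9, the median gene, was at 1.51 RPKM in library a and 4.38 in library b, S100a8 at 0.380 and 5.99, Retnlg at 0 and 0.551 and Mpo at 0.0195 and 0.225. Endothelial genes gave 2 higher and 0 lower of 11 in the authors' deposited table (3 and 0 when adjusted over the list alone), with a median of 0.44 on the log2 scale at percentile 99.97. They were Lyve1, which rose 1.98-fold (adjusted p = 0.00108), and Stab2, which rose 1.74-fold (adjusted p = 0.0222), in the authors' deposited table. Of 15 stellate cell and fibroblast genes, only the collagen gene Col3a1 passed, 2.10-fold higher (adjusted p = 0.000147) in the authors' deposited table and likewise when adjusted over the list alone, and the median log2 fold change of 0.14 was at percentile 88.4. Cholangiocyte genes gave 1 higher and 1 lower of 8 in the authors' deposited table and also when adjusted over the list alone, with a median of -0.27 on the log2 scale at percentile 2.64. Spp1, the osteopontin gene, which macrophages also express, rose 3.27-fold (adjusted p = 6.6e-10) and Krt23 was 3.15-fold lower (adjusted p = 0.0178) in the authors' deposited table. The 7 erythroid names are 5 distinct genes, since Hbb-b1 and Hbb-bs share a position, as do Hbb-b2 and Hbb-bt. Of the 5, 1 was lower in the authors' deposited table (2 when adjusted over the list alone), with a median log2 fold change of -0.40 at percentile 8.77. It was Alas2, of haem synthesis, which fell from 60.2 to 14.8 RPKM (adjusted p = 9.46e-22) in the authors' deposited table.

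Lipid metabolism showed a few large decreases among many small differences. Of 15 lipogenesis genes, 2 were higher and 2 were lower in the authors' deposited table (3 and 5 when adjusted over the list alone), with a median log2 fold change of -0.46 at percentile 0.365 of the random lists. Scd1, the stearoyl-CoA desaturase gene, fell from 2165 to 677 RPKM, 3.28-fold lower with an adjusted p of 1.13e-11, and the lipase gene Pnpla3 rose 5.41-fold from 0.279 to 1.55 RPKM (adjusted p = 1.54e-06) in the authors' deposited table. Of 18 genes of fatty acid oxidation, 1 was higher and 4 were lower in the authors' deposited table (1 and 6 when adjusted over the list alone), with a median of -0.32 on the log2 scale at percentile 6.17. The peroxisomal thiolase gene Acaa1b fell 4.17-fold, from 870.9 to 216 RPKM (adjusted p = 5.53e-24), in the authors' deposited table. Among 20 measured cholesterol synthesis genes, 1 was higher and 1 was lower in the authors' deposited table (1 and 2 when adjusted over the list alone), with a median of -0.24 on the log2 scale at percentile 11.2. Mvd, a decarboxylase gene of the pathway, was 1.77-fold higher (adjusted p = 0.00549) in the authors' deposited table. Bile acid genes gave 0 higher and 3 lower of 16 in the authors' deposited table (1 and 7 when adjusted over the list alone), with a median of -0.45 on the log2 scale at percentile 0.34. The transporter gene Abcc3 was 2.49-fold lower (adjusted p = 5.68e-10) and Cyp8b1, which sets the balance between bile acid species, was 1.91-fold lower (adjusted p = 0.000859) in the authors' deposited table. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 12.6 and 22.1 RPKM with an adjusted p of 0.0916 in the authors' deposited table.

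Genes expressed around the central vein were on balance lower. Of 13 pericentral genes, 5 were lower and 1 was higher in the authors' deposited table (7 and 1 when adjusted over the list alone), with a median log2 fold change of -0.56 at percentile 0.025. Lgr5 fell from 0.989 to 0.377 RPKM, 2.71-fold lower with an adjusted p of 2.21e-05, and Cyp2e1 fell from 3724 to 1892 RPKM, 2.03-fold lower with an adjusted p of 0.000315, in the authors' deposited table. Periportal genes went both ways, with 3 higher and 2 lower of 17 in the authors' deposited table (3 and 4 when adjusted over the list alone) and a median of -0.22 on the log2 scale at percentile 39. Ctsc was 2.25-fold higher (adjusted p = 0.000349), G6pc, the glucose-6-phosphatase gene, was 2.18-fold higher (adjusted p = 6.57e-05) and Cyp2f2 fell from 615 to 301 RPKM in the authors' deposited table.

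Circadian clock genes gave 1 higher and 6 lower of 17 in the authors' deposited table (1 and 7 when adjusted over the list alone), and their median log2 fold change of -0.51 lay below all 10000 random lists. Ciart fell 4.78-fold (adjusted p = 3.13e-06), Dbp fell 2.03-fold (adjusted p = 0.000289) and the activator gene Arntl rose from 1.11 to 2.09 RPKM in the authors' deposited table. The hours of collection of the 2 groups are not given in the sources used here.

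Of 7 measured fetal and tumour marker genes, 2 were higher and 0 were lower in the authors' deposited table, as also when adjusted over the list alone. Their median log2 fold change was -0.08, at percentile 14.5, while the mean was 0.88. Igf2, a fetal growth factor gene, rose from 0.0504 to 3.85 RPKM (adjusted p = 1.67e-34) in the authors' deposited table, 6.16 on the log2 scale and 4.71 for the RPKM ratio with a pseudocount of 0.1. Igdcc4 was at 0.0285 and 0.277 RPKM (adjusted p = 0.0317) in the authors' deposited table, but its recovered reads came mainly from 1 STAT5ca library (0.506 against 0.0476 RPKM in the other). Of 8 reference genes, 0 were higher and 0 were lower in the authors' deposited table, and 0 were higher and 3 lower when adjusted over the list alone. The 3 lower ones were Gapdh, at 725 RPKM in Null and 506 in STAT5ca, Hprt, at 40.2 and 26.7, and Pgk1, at 174 and 119, in the authors' deposited table. Actb was at 166 and 193 RPKM and Polr2a at 6.79 and 7.06 RPKM there. The list's median log2 fold change was 0.03, at percentile 82.0. That median includes Ppia, listed at 0.0349 and 0.130 RPKM, a value not read as a level of the gene.

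**Figure D2:**
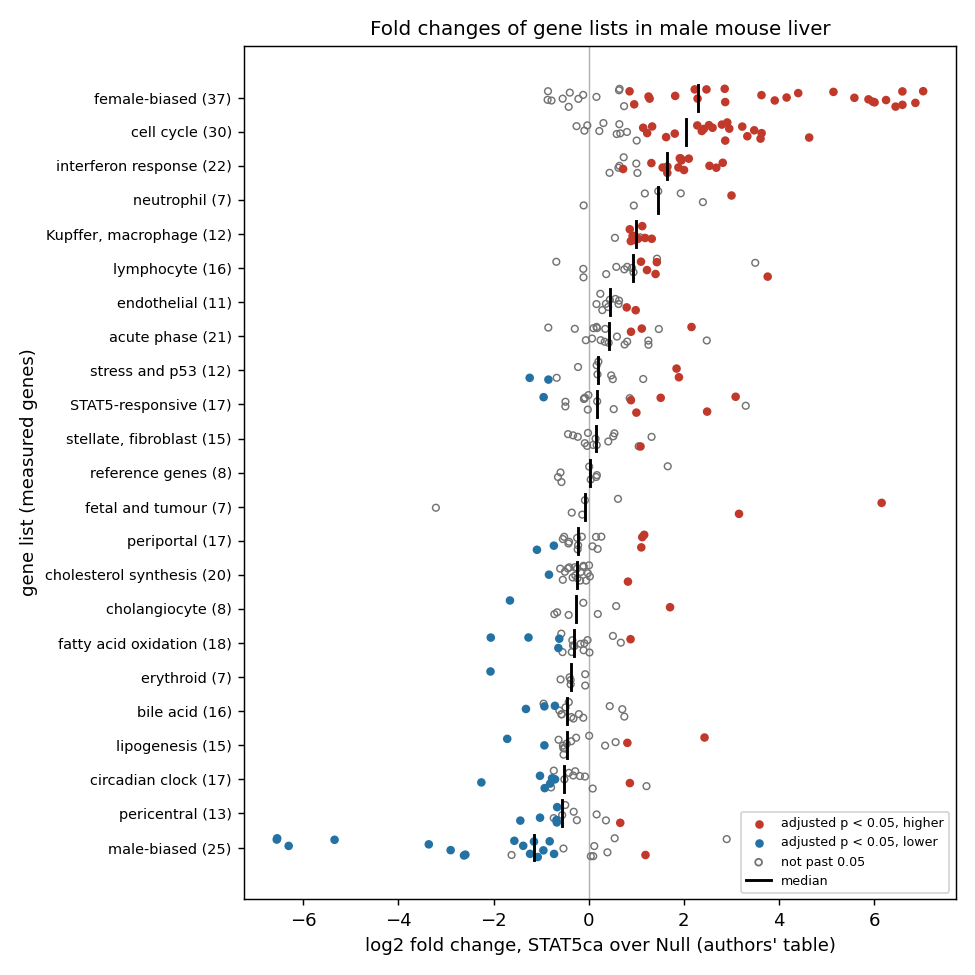
Log2 fold change of STAT5ca over Null from the authors' deposited table for 371 measured names of 23 lists, 1 point per name, filled where the adjusted p was below 0.05, with a black bar at each list's median. Medians run from -1.15 for male-biased genes to 2.29 for female-biased genes.

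Of the 23 lists, 15 had a median outside the range that holds 95% of their random lists. Random lists treat genes as independent, which genes of one pathway are not, so that these percentiles describe these libraries and are not p-values. The adjusted p-values rest on 2 samples per group and set each group difference against a spread estimated from these samples alone.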

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

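The alternatives below were chosen after the data were seen. The planned ones (other scalings, count filters and count tests, the other kind of count, the replicate block, each replicate left out, camera with other settings) were not run on the authors' deposited table, which has no values per sample; a count test, read minimums and fits without each library were run only on the genes with recovered reads, and the others not at all. No paired analysis was possible because its columns carry no replicate numbers. At an adjusted p below 0.01 the counts were 1444 genes, 1055 higher and 389 lower, the last down from 598 by construction of the threshold, and 1243 with at least a 2-fold change. Among genes with a mean of at least 1 RPKM, 986 were called instead of 2031, 535 of them higher and 451 lower, and 551 with at least a 2-fold change, since fewer genes were counted. Adjusted again over genes with a mean of at least 0.1 RPKM, 2104 were called, 1418 higher and 686 lower. With a pseudocount of 1 RPKM on the plain ratio, 402 of the calls reached 2-fold, against 1300 with 0.1, since a pseudocount shrinks low genes. Of the 59 named genes 22 moved by over 0.1 on the log2 scale on the RPKM ratio with a pseudocount of 0.1, and 58 of 58 kept their side of 0.05 when adjusted again. Itih4, Igdcc4, Gzma, Cxcr2, Stab2 and Krt23 did not reach 0.01, and 12 of 46 counts of list members moved by over 1.5 times there, such as lymphocyte genes from 5 to 1. The 15 lists outside the random 95% stayed so under the other matching and both pseudocounts, and cholangiocyte genes joined them under 2 of these 3. Over all 7 names, repeats of a locus included, the erythroid median was -0.38 on the log2 scale instead of -0.40. Of 6746 genes with recovered reads the authors called 823 and limma-voom 488, of which 481 are shared; none of the authors' calls tested in the lymphocyte (4), neutrophil (1), fetal and tumour (1) and cholangiocyte (1) lists was among them. With minimums of 10 and 50 reads limma-voom gave 438 and 370, against 885 and 621 for the authors. Leaving out 1 recovered library gave 373 (Null a), 316 (Null b), 228 (STAT5ca a) and 14 (STAT5ca b), with 994 at an unadjusted p below 0.05 in the last, the lone library being assumed to vary like the others; the cause was not tested. Depth limits short genes below about 0.1 RPKM, since 3 reads over a group give 0.0714 to 0.0773 RPKM for 1 kb; a longer gene has more reads at the same RPKM.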

Other observations

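The tests in this part were all chosen after the results had been seen, and so were the genes. Of 5 receptor genes looked at, 4 were higher in the authors' deposited table. Lifr, the receptor of leukaemia inhibitory factor, went from 26.8 to 297.5 RPKM, 10.8-fold higher with an adjusted p of 2.89e-51 in the authors' deposited table. The growth hormone receptor gene Ghr rose 2.11-fold (adjusted p = 0.00168), the leptin receptor gene Lepr 8.96-fold (adjusted p = 7.12e-11) and the oestrogen receptor gene Esr1 4.58-fold (adjusted p = 2.73e-16) in the authors' deposited table. The insulin receptor gene Insr was at 18.1 and 15.7 RPKM, with an adjusted p of 1 in the authors' deposited table. Secreted proteins went both ways. Serpina6, the corticosteroid-binding globulin gene, rose 23.4-fold from 142 to 3434 RPKM (adjusted p = 4.22e-50), and albumin, the most abundant of these, rose 1.70-fold from 31444 to 55114 RPKM (adjusted p = 0.0128) in the authors' deposited table. The thyroid hormone carriers Ttr and Serpina7 were 2.14-fold and 2.39-fold lower (adjusted p = 1.03e-05 and 1.74e-07) in the authors' deposited table. Cfd, the adipsin gene, fell from 12.4 to 0.642 RPKM and the carbonic anhydrase gene Car3 from 1953 to 393 RPKM, both past the threshold in the authors' deposited table.

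Of 7 imprinted genes looked at, 3 were called in the authors' deposited table, Igf2 among them. The imprinted gene Dlk1, in the fetal and tumour list like Igf2, is not among the 7. It was at 0.0107 RPKM in Null and at 0 in STAT5ca and was not called. Peg3 rose 14.9-fold (adjusted p = 6.85e-28) and Grb10 rose 8.44-fold (adjusted p = 3.23e-29) in the authors' deposited table. Plagl1, Mest, Ndn and Igf2r had an adjusted p of 1 in the authors' deposited table. Of the other milk protein genes looked at, Csn1s1, Csn3, Wap and Lalba were listed at 0 in both groups and Csn1s2a at 0.0705 RPKM in STAT5ca in the authors' deposited table. Within single gene families the direction differed. In the Cyp2c family 4 of 13 measured genes were higher and 5 were lower in the authors' deposited table: Cyp2c69 rose 48.0-fold and Cyp2c70 3.59-fold, while Cyp2c50 was 3.32-fold lower. In the Cyp3a family 6 of 9 were higher, and Cyp3a11, the most abundant of those named, was 2.43-fold lower in the authors' deposited table. All 5 measured Raet1 genes, which encode ligands of the NKG2D receptor, were lower, by 2.70 to 3.48 times, in the authors' deposited table. The listed positions of Raet1a, Raet1b and Raet1c overlap those of every other member, so these are not 5 separate decreases. Reads shared among paralogs leave single members of these families uncertain. Hmgcs1 was listed at 0 in both groups at a position on an unplaced part of chromosome 13, and the reference gene Ppia at 0.0349 and 0.130 RPKM at a position on chromosome 9 in the authors' deposited table, so neither value is read as a level of the gene.

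Reads recovered per library show how single libraries differ within a group. Among genes with at least 200 reads, the median absolute log2 difference between the 2 libraries of a group was 0.31 in Null and 0.23 in STAT5ca. Of 18 recovered calls among cell cycle genes, 15 also passed limma-voom at an adjusted p below 0.05. Ccnb1 was at 0.156 and 0.216 RPKM in Null and at 1.77 and 1.26 RPKM in STAT5ca. Nusap1 was at 0 and 0.0508 RPKM in Null and at 0.718 and 0.710 RPKM in STAT5ca. Without STAT5ca library b, limma-voom called 14 of the 6746 genes tested, against 488 with all 4 libraries. The neutrophil gene S100a8, not called by the authors, was at 0.380 RPKM in STAT5ca library a and at 5.99 RPKM in library b, against 0.795 and 0.770 RPKM in Null. The Kupffer cell gene Marco, not called either, was at 2.40 and 6.91 RPKM in STAT5ca and at 1.54 and 2.64 RPKM in Null. Krt23 was at 4.68 and 1.59 RPKM in Null and at 1.12 and 0.895 RPKM in STAT5ca.

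Markers of Kupffer cells were higher by a median of 1.00 on the log2 scale. A lower share of hepatocyte RNA would raise markers of every other cell type alike. As the whole cause it is argued against by the Kupffer median, which exceeded that of stellate cell and fibroblast markers by 0.85 on the log2 scale (12 and 15 genes, two-sided permutation p = 0.00838 over genes, which are not independent). The excess over endothelial markers was 0.55 (11 genes, p = 0.00017 by the same permutation test). Medians were above 0 for endothelial (0.44), lymphocyte (0.93) and neutrophil (1.46) genes too, and below 0 for cholangiocyte (-0.27) and erythroid (-0.40) genes. A smaller part of the rise could still come from that share, which was not tested. Blood left in the tissue is argued against by 4 distinct haemoglobin genes, whose median log2 fold change was -0.39 and the highest -0.07. More Kupffer cells, or more of these transcripts per cell in response to STAT5ca hepatocytes, remain open and were not tested.

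More genes were called higher than lower. A scaling between groups that favours STAT5ca would lift genes of every level, and is argued against as the whole cause by the calls at a mean of 10 RPKM or more, of which 36.2% of 412 were higher (95% confidence interval 31.5% to 41.0%, which treats genes as independent). Of these, 48.8% of the 172 with at least a 2-fold change were higher (41.2% to 56.6%), with no excess either way beyond that interval, and 27.1% of the 240 with a smaller change (21.6% to 33.2%), the ones such a scaling would lift most readily. The share of higher calls was 31.7 percentage points larger below a mean of 1 RPKM (85.9%) than at or above it (54.3%). Little-expressed genes having more room to rise than to fall could give such a gap. The share fell further with level, to 25.95% of 131 calls above 100 RPKM, which that explanation does not need, so a decrease of abundant liver transcripts may add to it as an untested second part. The median log2 fold change of all measured genes, called or not, fell with level too. It was 0.29 from 0.1 to 1 RPKM, -0.01 from 1 to 10 RPKM and -0.20 above 100 RPKM. Room to fall limits which genes can be called, and does not by itself account for a shift of this median. Whether a lower share of hepatocyte RNA adds to this was not tested.

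Around A1bg, called genes formed a chain on chromosome 15 between 60525567 and 61024057 (mm9), in which 42 of 52 measured genes were called, each of the 42 higher in STAT5ca in the authors' deposited table. They were A1bg, Lratd2, which rose 6.13-fold, and 40 numbered noncoding transcripts. The largest chain in 1000 shuffles of the calls held 9, which argues against chance placement of independent rows. The shuffles treat neighbouring rows as independent, which closely spaced noncoding rows may not be, since several can be pieces of 1 transcript. Of the STAT5ca reads of the 44 genes of the chain that could be recovered, called or not, library a held 49.5% (1246, against 1271 in library b, 8 and 13 in Null). The 34 called genes among them held most of these reads, 1223 and 1247. They cannot decide against reads of 1 STAT5ca library alone, since every recovered call showed both libraries apart from Null. All 890 had both STAT5ca libraries above both Null libraries if called higher, and below both if called lower. The 10 genes not called held few reads, 23 in library a and 24 in library b, which argues against reads of 1 library alone for these 10. The longest run of consecutive calls in one direction, 18 against at most 5 in the shuffles, lay beyond A1bg, from 60957050 to 61347401. A hypothesis is that the whole region may become active with A1bg; transcription running on from A1bg and separate start sites were not told apart, since the table lists no strand. Shorter chains of higher calls lay around Cyp2b9 and Cyp2a4 (12 of 25 measured genes called higher) and around Socs2 (9 of 13). A chain of lower calls covered part of the Mup cluster (28 of 65), and Mup7, also called lower, lay outside it.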
